A study of Homo sapiens with 3 samples.

How the data were processed

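Immune cells of 3 human livers with metabolic dysfunction-associated fatty liver disease (MAFLD, fat storage in the liver together with metabolic disease) were measured by droplet sequencing. Per the labels' protocols, liver tissue was digested, sorted by flow cytometry for CD45, the surface protein of white blood cells, and sequenced with the v2 Chromium chemistry of 10x Genomics, which counts the 3′ ends of transcripts. The labels call the libraries single nuclear in the protocol and single cell in the library source; the median share of mitochondrial UMIs per barcode was 5.27%, 6.25% and 6.09% in livers 1, 2 and 3. The livers form 1 group with 3 replicates and no control group, so no comparison between groups of people was made.

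The deposited files hold raw UMI counts per gene and cell barcode (a UMI marks 1 captured RNA molecule), made by the authors with Cell Ranger 3.0.2 and GRCh38 per the submitters' processing notes. The annotation release behind the counts is not given in the sources used here. Each matrix lists 33694 genes, and its lowest barcode held 500, 501 and 500 UMIs. The libraries held 67154294, 41359796 and 40255761 UMIs over 10781, 9480 and 8637 barcodes. Coordinates and gene types were taken from GENCODE 29 on GRCh38 by Ensembl identifier, and 2 listed genes were matched by identifier under the files' older symbols.

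Cells were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which removed 196, 336 and 449 barcodes. Scrublet, run in scanpy 1.11.5 per liver, called 0, 0 and 1 doublets with its automatic threshold. That is under 0.5% of cells and was taken as a failed call. The highest Scrublet scores were therefore removed at 0.8% per 1000 barcodes, 913, 693 and 566 cells, leaving 9672, 8451 and 7622 cells.

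Cells of the 3 livers were clustered together with no integration, first all cells and then phagocytes and lymphocytes apart (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, seed 1, python-igraph 0.11.9). Genes of the 20 fixed test lists were kept out of the clustering features. A cluster's score for a class was the mean over the class markers of the z-score of its mean log-normalised expression across clusters. A name needed a score of at least 0.8 and at least 3 markers detected in 20% of cells. It was refused where another class had more markers among the top 10 genes. Phagocyte clusters with a T or NK score of at least 1 were called mixed. Markers, lists, tests, the rule for named genes and most alternatives were fixed before the data were examined, whereas the scoring rule and its threshold of 0.8 were set after the clusters had been seen.

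The threshold left 3 phagocyte clusters (P1, P3 and P11) without a name, with 285, 16 and 312 cells in livers 1, 2 and 3, and 3 lymphocyte clusters (L4, L6 and L16) with 410, 410 and 128 cells. With no integration, many clusters came mostly from 1 liver or from livers 1 and 3. Monocyte-derived-like cells came from cluster P0 in livers 1 and 3 and P17 in liver 2. CD8 T-like cells came from L3, L5 and L7 in livers 1 and 3 and L15 in liver 2. CD16 NK-like cells came from L8 and from L18 in liver 2, and CD56bright NK-like cells from L1, L2 and L13, each mostly of 1 liver. Kupffer-like cells came from P5 and P12; P12 held 39 cells with a median of 990 UMIs and 0.340% mitochondrial UMIs. A difference from the study's own cell types can come from these rebuilt names.

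UMI counts were summed per liver and class where at least 20 cells were present and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood test with the liver as a block, Benjamini-Hochberg adjustment at 0.05). All classes of a lineage shared 1 estimate of the spread. Genes used as clustering features or class markers were left out of every count and list, since they define the classes. The 3 comparisons were monocyte-derived-like against Kupffer-like cells, CD8 T-like against CD16 NK-like cells, and CD56bright NK-like against CD16 NK-like cells; the last 2 share their CD16 NK-like libraries. Kupffer-like cells numbered 327, 4 and 50, so that class entered with livers 1 and 3 only, although the design had asked for all 3 livers. The rule that a named gene change the same way in all livers was read there as both livers holding both classes. Regulatory T-like cells were too few in liver 3 and stayed out of the fit.

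Standard errors of log2 fold changes were computed as the fold change over the square root of the test's F value. CPM, the counts of a sum scaled to the same total in every sum, are given as mean ± SD over livers, with n = 3 except for Kupffer-like cells, where n = 2. Folds against 0 UMIs were set against 3 UMIs over the class and are lower bounds, and ratios against 1 to 3 UMIs carry a 95% counting interval. Shares of cells carry exact Clopper-Pearson 95% intervals from scipy 1.17.1. Intervals and bounds cover counting error only. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a comparison. Camera compares a list with the other genes tested, whereas fry asks whether the list changes at all. List genes could not be clustering features, while other variable genes were features and were left out. The background of camera thus held fewer genes that vary between classes, so its p-values can be too small for every list. The classes were also drawn by clustering the same cells, so genes that vary with the clustering features can differ for that reason. The p-values of genes and lists thus describe classes already drawn apart. Genes named are, per list, up to 2 with the largest positive and up to 2 with the largest negative change past the threshold, and per comparison the 5 highest and 5 lowest with at least 50 CPM in 1 class.

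The liver was kept as a block because both classes of a comparison come from the same livers. The checked deviations of paired libraries correlated at 0.0834 and 0.128 for livers 1 and 3 in the phagocytes, at 0.587, 0.750 and 0.610 for CD8 T-like with CD16 NK-like cells, and at 0.610, 0.752 and 0.612 for CD56bright with CD16 NK-like cells. The test was run on simulated counts with 200 changed genes per comparison. Of changes of log2 1 and log2 2 it recovered 36% and 82% for the phagocytes (9140 genes, 7.09% of calls false), 81% and 94% for CD8 T-like cells (11825 genes, 4.37% false) and 72% and 91% for CD56bright NK-like cells (11814 genes, 2.40% false). In this single run, genes were drawn independently, each with the spread typical of its level, and classes were given. The rates thus do not cover correlated genes, gene-specific spread or classes clustered from the same cells.

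Alternatives were RLE factors, DESeq2 1.42.0, no filter on low counts, no block, only the 2 classes compared, sums thinned to equal UMIs, each liver left out in turn, other doublet and cell filters, other resolutions, each liver clustered on its own, list genes among the features, and count splitting. Clustering each liver on its own changed the second level only, with the first level still joint. Naming thresholds of 0.5 and 1 and the class without cluster P12 were added after the data had been seen. A total of 748 genes that can tell people apart, among them variable segments of antigen receptors, were never tested. Reads of HLA genes, HSPA1A and HSPA1B, FCGR1A, and CCL3 and CCL4 with their copies CCL3L3 and CCL4L2 can be shared among near-identical sequences or alleles, so their levels are uncertain. A few genes that the rule would name are not reported here.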

Results

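CD45-positive cells of 3 livers with MAFLD were profiled, and 9672, 8451 and 7622 cells were kept for livers 1, 2 and 3. The libraries held 67154294, 41359796 and 40255761 UMIs, with a median of 4293, 3432 and 3695 UMIs and 1694, 1316 and 1484 genes per barcode. The series title names monocyte-derived macrophages as the cells of interest. Whether the class called monocyte-derived-like here holds those macrophages or monocytes was not tested. It was named by S100A8, S100A9, VCAN, FCN1 and other markers. C1QC averaged 17.3 CPM in it against 10884 in Kupffer-like cells, and of 11 macrophage transcription factors 6 were lower and 2 higher. The comparison of these classes may thus be one of monocytes with macrophages. The unnamed phagocyte clusters, such as P3 and P11, lie outside the monocyte-derived-like class. All 3 livers belong to 1 group, so cell classes were compared within livers.

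CD8 T-like cells (24.4% ± 5.29 of kept cells, SD, n = 3) and CD56bright NK-like cells (24.0% ± 4.88) were the most frequent classes. CD56bright NK-like cells were named by XCL1, XCL2, CD160, NCAM1, KLRC1 and IL2RB, genes of the less cytotoxic branch of natural killer cells. CD4 T-like cells made up 14.6% ± 4.50, MAIT-like cells, T cells that recognise microbial vitamin B metabolites, 7.47% ± 6.39, and CD16 NK-like cells 5.73% ± 1.88. Among phagocytes, cDC2-like dendritic cells made up 4.0% ± 1.68, monocyte-derived-like cells 2.28% ± 0.459 and non-classical monocyte-like cells 1.5% ± 0.266. B cell-like cells held 1.90% ± 0.920 and plasma cell-like cells 1.09% ± 0.730. The sort on CD45 and the digestion can set these shares. The CD8 T-like share was 6.20% with a naming threshold of 1, because clusters L5, L7 and L15 scored 0.846, 0.942 and 0.884, and 14.1% with no doublets removed and 15.2% with each liver clustered on its own. With list genes among the features the cDC2-like share was 2.19%, and the monocyte-derived-like share was 3.52% to 3.62% with the stricter filter, count splitting or resolution 0.5.

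Kupffer-like cells, the resident macrophages of the liver sinusoids named here by MARCO, CD5L, TIMD4 and 6 other markers, varied widely between livers. They made up 3.38% (95% interval 3.03 to 3.76) of cells in liver 1, 0.0473% (0.0129 to 0.121) in liver 2 and 0.656% (0.487 to 0.864) in liver 3. Monocyte-derived-like cells, named by S100A8, S100A9, VCAN, FCN1 and 4 other markers, ranged from 1.88% to 2.78%, but in liver 3 they numbered 298 to 370 cells (3.64% to 4.79%) under 7 alternatives in place of 166. Of Kupffer-like plus monocyte-derived-like cells, Kupffer-like cells were 54.9% (50.8 to 58.9), 2.45% (0.673 to 6.16) and 23.1% (17.7 to 29.4) in livers 1, 2 and 3. Over the alternatives these shares ran from 41.3% to 60.9%, 0% to 2.87% and 9.02% to 29.3%, and that of liver 3 was 9.02% to 14.4% with the stricter cell filter, count splitting, resolution 0.5, list genes among the features, the automatic Scrublet threshold or no doublets removed. Phagocytes in unnamed clusters added 2.95%, 0.189% and 4.09% of cells. With the naming threshold at 0.5 the Kupffer-like cells numbered 447, 4 and 144, since cluster P11 then joined the class.

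**Figure D1:**
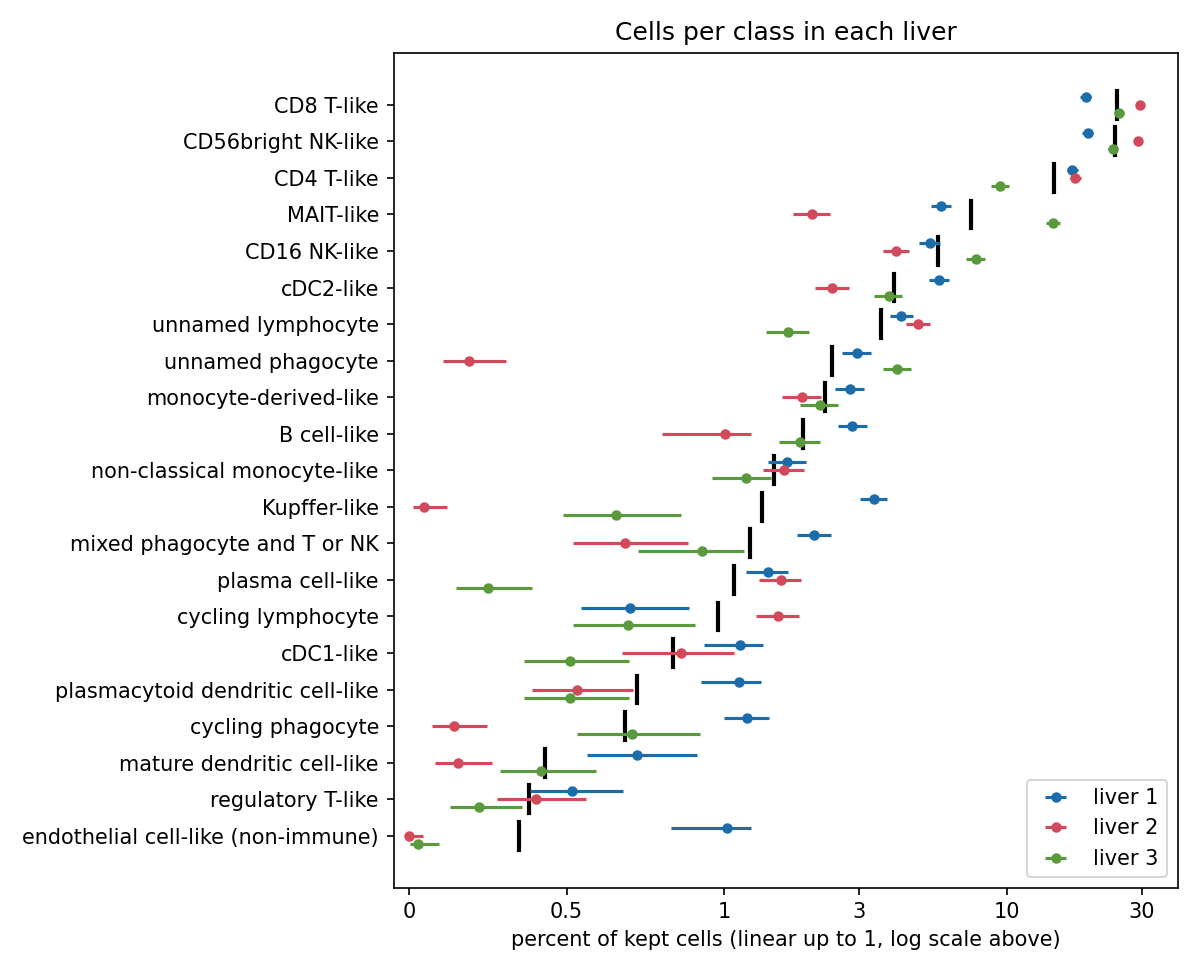
Percent of kept cells (x axis, linear to 1% and logarithmic above) in each cell class (y axis). Points are the 3 livers with exact 95% intervals and black ticks are means; the Kupffer-like points lie at 3.38%, 0.0473% and 0.656%, the monocyte-derived-like points between 1.88% and 2.78%.

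The first comparison asked how monocyte-derived-like cells differed from Kupffer-like cells of the same livers. Between these classes, 6 markers of mononuclear phagocytes at large had a median log2 fold change of −1.66 (−3.47 to 0.32). The C1q chains, which start the classical complement pathway, stood far lower in monocyte-derived-like cells: C1QC averaged 17.3 ± 13.1 CPM there (SD, n = 3) and 10884 ± 3130 CPM in Kupffer-like cells (n = 2), and C1QB averaged 26.7 ± 28.7 against 11707 ± 1084 CPM. APOE, the apolipoprotein of lipid export, averaged 3.74 ± 2.06 against 2666 ± 1342 CPM. In the other direction, SLC11A1, a metal transporter of phagosomes, averaged 236 ± 49.5 against 1.32 ± 1.86 CPM, and CXCL8, the neutrophil chemoattractant interleukin 8, 503 ± 186 against 31.8 ± 13.3 CPM. EREG, an epidermal growth factor receptor ligand, averaged 103 ± 34.4 CPM in monocyte-derived-like cells and had 0 UMIs in Kupffer-like cells, at least 115-fold higher.

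By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 958 genes were higher and 1131 lower in monocyte-derived-like cells among 7703 tested. C1QC (ENSG00000159189, chromosome 1, 22643630 to 22648110) differed by a log2 fold change of −9.80 (SE 0.52, adjusted p = 9.2e-12), APOE (ENSG00000130203, chromosome 19, 44905754 to 44909393) by −9.85 (SE 0.74, adjusted p = 9.4e-10) and SLC11A1 (ENSG00000018280, chromosome 2, 218382029 to 218396894) by 6.39 (SE 0.43, adjusted p = 1.9e-10). AXL (ENSG00000167601, chromosome 19, 41219203 to 41261766), a receptor for clearing dying cells, had 0 UMIs in monocyte-derived-like cells and 376 ± 7.82 CPM in Kupffer-like cells, at least 344-fold lower. IGF1, ITGB5 and SUCNR1 likewise had 0 UMIs there and were at least 54.5-fold, 65.6-fold and 63.4-fold lower. CXCL12 (ENSG00000107562, chromosome 10, 44370165 to 44386493), a chemokine that retains leukocytes, had 1 UMI against 2974, a ratio of 2407 (432 to 95100). TMEM154 had 0 UMIs in Kupffer-like cells and was at least 64.3-fold higher in the other class. SULF2, a sulfatase of heparan sulfate, and TRAF3IP3 were higher with ratios of 295 (52.5 to 11712) and 119 (40.5 to 583). Kupffer-like cells came from livers 1 and 3 only (327 and 50 cells), and without liver 1 the counts were 280 and 292. Without the liver block they were 512 and 633, with only the 2 classes in the fit 596 were higher, and with sums thinned to equal UMIs they were 449 and 459.

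Complement and antigen presentation genes were lower in monocyte-derived-like cells. Of 10 measured complement genes, 9 were lower and 1 was higher, and 9 and 1 when adjusted over the list alone (median log2 fold change −2.71). The higher gene was C5AR1, the receptor of the chemoattractant C5a (log2 1.51, SE 0.45). Of 10 MHC class II genes, which present peptides to CD4 T cells, 9 were lower and 0 higher, and 9 and 0 when adjusted over the list alone (median −2.22). HLA-DPA1 averaged 1458 ± 498 against 7905 ± 774 CPM (log2 −2.74, SE 0.15) and HLA-DQA1 differed by −2.99, with HLA levels uncertain because alleles differ from the reference. CIITA, the master regulator of these genes, did not pass (log2 −0.07). Beside this group, 5 cDC1 markers had a median log2 fold change of −3.83 (−8.34 to −0.75), 6 cDC2 markers −1.87 (−5.89 to 2.16) and 2 mature dendritic cell markers −4.07 (−5.71 to −2.43). Of 12 interferon response genes 9 were lower, among them IFIT1 (−3.10) and IFIT2 (−2.53), and 1 was higher, MX2 (0.93). Adjusted over the list alone 11 were lower and 1 higher (median −1.05). Limma camera gave adjusted p = 9.4e-10 for complement, 2.4e-13 for MHC class II and 6.3e-05 for interferon response. Its background lacked the variable genes used for clustering, so these values can be too small. For complement, C1QA, C1QB and C1QC were also among the leading genes of the first-level cluster named Kupffer. The calls were lost in camera with an estimated correlation, with adjusted p = 0.0841 for the first and second and adjusted p = 0.124 for the third. With list genes among the features, 1 gene of each of the complement and MHC class II lists was left, and camera gave adjusted p = 0.0917 and 0.653, with a log2 fold change of 0.28 for the latter. By edgeR's quasi-likelihood test or DESeq2, C5AR1 lost its call under 6 alternatives (adjusted p = 0.0524 to 0.217), and MX2 without liver 1 (0.123), with no liver block (0.106) and with the automatic Scrublet threshold (0.0537).

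Inflammatory, glycolytic and immediate-early genes were higher in monocyte-derived-like cells. Of 10 inflammatory genes, 6 were higher and 1 lower, the same counts as when adjusted over the list alone (median 2.12). The 2 with the largest increases were PTGS2, the inducible cyclooxygenase (log2 4.56, SE 0.42), and OSM, a cytokine of the interleukin 6 family (4.30, SE 0.73). IL18, an inflammasome product, was lower (−2.29, SE 0.20), and TNF did not pass (0.51). Of 11 glycolysis genes 6 were higher and 1 lower, also when adjusted over the list alone (median 0.79). SLC2A3, a glucose transporter, averaged 203 ± 29.1 against 3.89 ± 1.02 CPM and GAPDH 3910 ± 335 against 795 ± 167 CPM, while PFKFB3 was lower (−2.32). Of 14 dissociation and immediate-early genes 9 were higher, among them ATF3 (2.67) and EGR1 (1.87), and 2 were lower, HSPA1B (−1.42) and HSPA1A (−1.10), near-identical copies whose counts are uncertain. The counts were 9 and 2 when adjusted over the list alone (median 1.06). In limma camera the inflammatory list had adjusted p = 5.3e-04, the glycolysis list 1.9e-04 and the dissociation list 2.5e-04. With an estimated correlation these became adjusted p = 0.0841, adjusted p = 0.124 and adjusted p = 0.124. Without liver 1, edgeR's quasi-likelihood test gave adjusted p = 0.344 for PTGS2, 0.164 for OSM, 0.467 for HSPA1B and 0.0819 for HSPA1A, and with no liver block it gave 0.626 and 0.295 for the last pair, 0.163 for ATF3 and 0.398 for EGR1. With list genes among the features, 2 inflammatory genes were left, with a mean of −0.76 and adjusted p = 0.341 by camera.

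Lipid handling genes were mostly lower in monocyte-derived-like cells. Of 16 measured genes of lipid uptake, storage and efflux, 10 were lower and 4 higher, also when adjusted over the list alone (median −1.37, limma camera adjusted p = 1.9e-04). That call was lost in camera with an estimated correlation (adjusted p = 0.124) and with list genes among the features, which left 2 genes (adjusted p = 0.0917). Besides APOE, PPARG, a nuclear receptor of lipid storage, was lower with 1 UMI and a ratio of 79.3 (13.9 to 3164). G0S2, an inhibitor of triglyceride breakdown, was among the higher genes (log2 3.63, SE 0.41). PLIN2, which coats lipid droplets, did not pass (−0.10). Of 7 measured genes of lipid-associated macrophages, the type described in fatty tissue, 3 were lower, among them GPNMB (−7.94) and CD63 (−2.69), and 2 were higher, CD9 (3.19) and LGALS3 (0.65), also when adjusted over the list alone. The median was −0.56 and limma camera gave adjusted p = 0.0970, or 0.344 with an estimated correlation. TREM2, the lipid receptor of that type, averaged 1.58 and 7.81 CPM and did not pass (log2 −0.56). The list passed under 6 alternatives (adjusted p = 3.1e-05 to 0.0134 by limma camera or fry). Among them were fry (0.0042), which asks another question than camera, and the fit without liver 1 (mean log2 fold change −2.18). By edgeR's quasi-likelihood test or DESeq2, CD9 lost its call under 4 alternatives (adjusted p = 0.193 to 0.959), among them without liver 1 (0.729), and had a log2 fold change of −0.61 with the naming threshold at 0.5, while LGALS3 lost its call under 4 (adjusted p = 0.0621 to 0.406), the lowest without liver 1.

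Receptors, chemokines, growth factors and iron genes went both ways. Of 12 phagocytosis receptors 7 were lower and 5 higher, also when adjusted over the list alone (median −1.54, limma camera adjusted p = 0.131, or 0.410 with an estimated correlation). MRC1, the mannose receptor, had 3 UMIs in monocyte-derived-like cells against 1402, a ratio of 378 (129 to 1836), while STAB1, a scavenger receptor (3.81), and FCGR1A, the high-affinity IgG receptor with near-identical copies (3.27), were higher. Of 11 chemokines 4 were higher and 3 lower, with 4 and 4 when adjusted over the list alone (median −0.08, camera adjusted p = 0.853, or 0.869 with an estimated correlation). CCL20 had 21 against 0 UMIs, at least 8.65-fold higher. CXCL9 was lower (−3.42) in 1 of 2 livers. Of 11 growth factor and matrix genes 3 were higher, with EREG and THBS1, an adhesive matrix protein (ratio 242, interval 43.0 to 9614), and 5 lower, with IGF1 and the protease MMP14 (−2.73), also when adjusted over the list alone (median 0.19, camera adjusted p = 0.876, or 0.875 with an estimated correlation). Of 9 iron genes 1 was higher, SLC11A1, and 4 lower, among them the haem-degrading HMOX1 (−3.00) and the ferritin chain FTL (−2.07), with 1 and 5 when adjusted over the list alone (median −0.39, camera adjusted p = 0.0518, or 0.124 with an estimated correlation). The receptor list passed under 7 alternatives (adjusted p = 2.2e-06 to 0.0147 by limma camera or fry), the highest without liver 1, and the iron list under 8 (0.00237 to 0.04997), while without liver 1 the mean of the iron list was 0.65 in place of −0.09, with adjusted p = 0.0269. With the naming threshold at 0.5, STAB1 had a log2 fold change of 0.50 (adjusted p = 0.26 by edgeR's quasi-likelihood test) and FCGR1A one of 0.66 (adjusted p = 0.183). In edgeR's quasi-likelihood test without liver 1, CCL20 had adjusted p = 0.641, CXCL9 a log2 fold change of 2.90 and MMP14 adjusted p = 0.0588, and without liver 3, THBS1 had adjusted p = 0.134. CXCL9 lost its call under 9 other alternatives (adjusted p = 0.0517 to 0.598 by edgeR or DESeq2), CCL20 with DESeq2 (0.562) and with no liver block (0.0700), and IGF1 with DESeq2 (0.0534).

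Of 11 macrophage transcription factors, 6 were lower and 2 higher, also when adjusted over the list alone (median −2.11, limma camera adjusted p = 0.0030, or adjusted p = 0.132 with an estimated correlation). NR1H3, the oxysterol receptor LXR alpha, averaged 5.85 ± 2.21 against 384 ± 16.6 CPM (log2 −6.03, SE 0.42), and SPIC, a factor of iron-recycling macrophages, had 1 UMI and a ratio of 116 (20.4 to 4603). NR4A1 (2.64) and ZEB2 (0.54) were higher. Of 12 oxidative phosphorylation genes 4 were higher, among them COX4I1 (0.64) and ATP5F1A (0.63), and 1 was lower, NDUFA4 (−0.76), also when adjusted over the list alone (median 0.10, camera adjusted p = 0.234, or 0.410 with an estimated correlation and 0.0291 with no filter on low counts). ZEB2 lost its call under 8 alternatives by edgeR's quasi-likelihood test or DESeq2 (adjusted p = 0.0541 to 0.123), among them without liver 1 (0.123) and without liver 3 (0.0674). ATP5F1A lost it without liver 1 (edgeR adjusted p = 0.222) and with sums thinned to equal UMIs (0.0616), COX4I1 with only the 2 classes in the fit (0.0592) and NDUFA4 with the naming threshold at 0.5 (0.0799). Beside these groups, 6 hepatocyte markers had a median log2 fold change of −1.39 (−2.30 to 1.51) and 4 T cell markers a median of 1.01 between the same classes. The median was 4.0 for 3 CD16 NK markers (−4.78 to 7.89), 1.56 for 3 MAIT markers, −2.24 for 6 non-classical monocyte markers (−7.84 to −0.66) and 2.96 for 2 B cell markers.

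**Figure D2:**
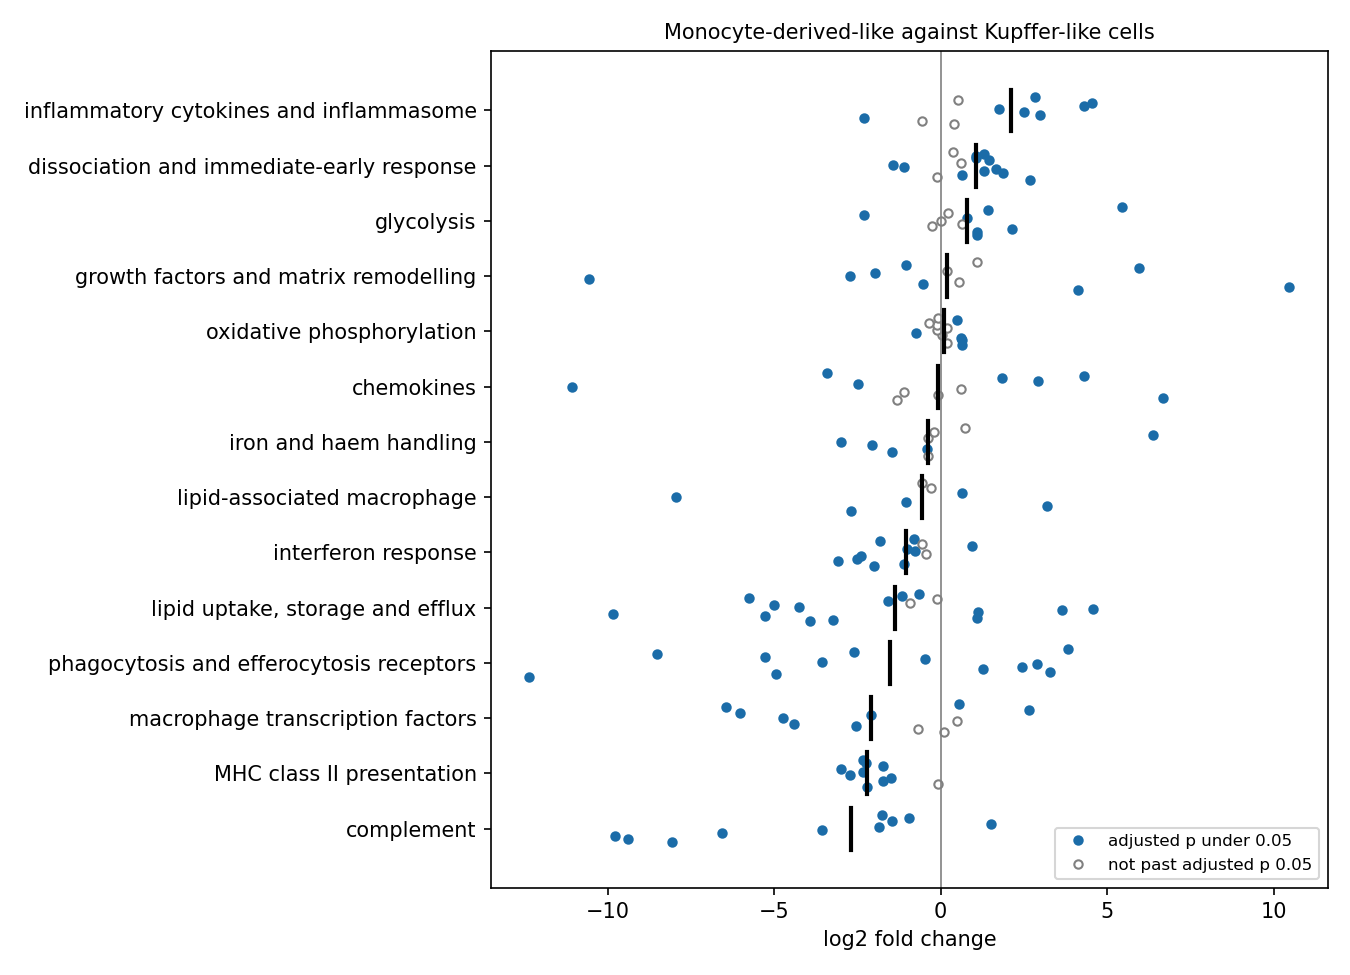
Log2 fold change (x axis) of each measured member of the fixed lists (y axis), monocyte-derived-like against Kupffer-like cells. Filled points had adjusted p under 0.05, open points did not, and black ticks mark list medians, from −2.71 for complement to 2.12 for inflammatory genes.

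The second comparison set CD8 T-like cells, the killer branch of T cells, against CD16 NK-like cells, the circulating killer cells of innate immunity, to describe the lymphocytes of the same livers. PDCD1, the inhibitory receptor PD-1, averaged 60.9 ± 19.8 CPM in CD8 T-like cells and 3.57 ± 4.93 CPM in CD16 NK-like cells (SD, n = 3 each). CXCR6, a receptor that holds lymphocytes in liver sinusoids, averaged 145 ± 16.6 against 16.1 ± 4.84 CPM, and RGS1, a brake on chemokine signals, 178 ± 32.6 against 22.9 ± 8.93 CPM. GNLY, a pore-forming granule protein, averaged 1666 ± 597 against 10547 ± 1185 CPM and GZMB, the protease granzyme B, 273 ± 94.3 against 1764 ± 452 CPM. HAVCR2, the inhibitory receptor TIM-3, averaged 7.02 ± 1.07 against 125 ± 25.1 CPM.

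By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1027 genes were higher and 1005 lower in CD8 T-like cells among 10271 tested. PDCD1 (ENSG00000188389, chromosome 2, 241849881 to 241858908) differed by log2 4.09 (SE 0.45, adjusted p = 4.6e-06), CXCR6 (ENSG00000172215, chromosome 3, 45940933 to 45948353) by 3.36 (SE 0.24, adjusted p = 9.4e-08) and HAVCR2 (ENSG00000135077, chromosome 5, 157085832 to 157142869) by −3.98 (SE 0.16, adjusted p = 8.8e-11), each in 3 of 3 livers. Others among the 5 highest were UBASH3A, a negative regulator of T cell receptor signalling (3.63), and LTB, a cytokine of lymphoid tissue (2.96). CEBPD (−3.08) and the integrin ITGAM (−2.10) were among the 5 lowest with GNLY and GZMB. Without liver 1 the counts were 431 and 445, and without liver 2 the lower count was 655. Without the liver block they were 284 and 245, with sums thinned to equal UMIs 547 and 498, and with count splitting 652 were lower. In edgeR's quasi-likelihood test without the block, GNLY had adjusted p = 0.0855, GZMB 0.0551 and CEBPD 0.168.

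On average over the class, residency genes were higher and circulation and cytotoxic genes lower in CD8 T-like cells. The class pools unlike clusters whose mix differs by liver. Cluster L5, with 404, 1 and 1068 cells in livers 1, 2 and 3, had KLF2, GZMH and S1PR1 among its leading genes. Cluster L3, with 1322, 14 and 364 cells, had GZMK and PDCD1 among them. Of 10 residency genes 8 were higher and 0 lower, also when adjusted over the list alone (median 1.79), with CD101 (3.49) and CXCR6 the largest. ITGAE, the integrin of epithelial resident T cells, did not pass (−0.04). Of 8 circulation genes 5 were lower and 0 higher, also when adjusted over the list alone (median −0.76), with CXCR1 (−3.04) and S1PR5, a receptor for exit from tissue (−1.71), the largest. S1PR1 did not pass (−0.42). Of 11 cytotoxic genes 8 were lower and 0 higher, also when adjusted over the list alone (median −0.89), while GZMA (−0.10) and GZMH (0.43) did not pass. Limma camera gave adjusted p = 3.1e-13 for residency, 5.6e-09 for circulation and 2.7e-11 for cytotoxic genes. With an estimated correlation these were adjusted p = 0.0084, 0.0168 and 0.0084. GNLY, GZMB and S1PR5 of these lists were also among the leading genes of the CD16 NK-like cluster L8, so the values are no separate support for that class. With no liver block, CD101 had adjusted p = 0.0858 and S1PR5 0.364 by edgeR's quasi-likelihood test.

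Of 8 inhibitory receptors 4 were higher and 1, HAVCR2, was lower in CD8 T-like cells, also when adjusted over the list alone (median 0.90). The list had adjusted p = 0.511 in limma camera, or 0.516 with an estimated correlation, and passed with the stricter cell filter, the automatic Scrublet threshold or no doublets removed (0.0348 to 0.0436). Besides PDCD1, CTLA4 was higher, with 3 UMIs in CD16 NK-like cells and a ratio of 13.6 (4.59 to 66.6), while TIGIT (−0.11) and TOX (−0.03) did not pass. Of 12 cytokines and chemokines 7 were higher and 2 lower, or 9 and 2 when adjusted over the list alone (median 0.64). LTB and IL32 (1.67) were the largest of the higher genes, and CCL3 (−1.73) and CCL4 (−0.57), with near-identical copies, were lower; IFNG did not pass (0.69). Of 11 transcription factors 6 were lower, among them NFIL3 (−1.87) and HOPX (−1.75), and 1 was higher, IKZF3 (0.38), also when adjusted over the list alone (median −0.80). Of 14 dissociation genes 8 were higher and 0 lower, with 9 and 1 when adjusted over the list alone (median 0.54), led by EGR1 (1.44) and JUN (1.28). The limma camera values were adjusted p = 4.6e-05 for cytokines, 4.0e-06 for transcription factors and 3.1e-07 for dissociation genes, and 0.0360, 0.0207 and 0.0433 with an estimated correlation. The transcription factor list lost its call with list genes among the features, which left 2 genes (camera adjusted p = 0.109). In edgeR's quasi-likelihood test, CCL4 lost its call under 7 alternatives (adjusted p = 0.0552 to 0.694), with 0.105 without liver 1 and 0.0988 without liver 2, and IKZF3 under 4 (0.0552 to 0.443), with 0.0694 and 0.0710. EGR1 had adjusted p = 0.126 without liver 1 by edgeR and 0.537 with no liver block, where NFIL3 had 0.0833 and HOPX 0.0536. Beside these groups, 6 hepatocyte markers had a median log2 fold change of 1.42 (0.56 to 2.27) and the globin genes HBA1 and HBA2 a median of −1.31. The median was −2.22 for 3 neutrophil markers (−3.72 to 3.79), 1.07 for 5 monocyte-derived markers (0.02 to 9.94), 3.89 for 7 CD4 T markers, 1.63 for 4 regulatory T markers and −1.55 for 7 MAIT markers (−4.84 to 4.58).

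The third comparison set CD56bright NK-like cells against the same CD16 NK-like cells. GZMB averaged 30.1 ± 30.7 CPM in CD56bright NK-like cells and 1764 ± 452 CPM in CD16 NK-like cells (SD, n = 3 each), and GNLY 411 ± 367 against 10547 ± 1185 CPM. S1PR1, the receptor that guides lymphocytes out of tissue, averaged 4.29 ± 3.44 against 212 ± 43.6 CPM. CXCR6 averaged 407 ± 84.6 against 16.1 ± 4.84 CPM, TOX2, a transcription factor of NK cell maturation, 162 ± 73.7 against 4.18 ± 4.24 CPM, and the immediate-early factor FOS 3432 ± 370 against 638 ± 86.4 CPM.

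By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1084 genes were higher and 999 lower in CD56bright NK-like cells among 10271 tested. GZMB (ENSG00000100453, chromosome 14, 24630954 to 24634267) differed by log2 −6.08 (SE 0.41, adjusted p = 1.6e-08), S1PR1 (ENSG00000170989, chromosome 1, 101236865 to 101243713) by −5.68 (SE 0.29, adjusted p = 6.4e-10) and TOX2 (ENSG00000124191, chromosome 20, 43914864 to 44069616) by 5.19 (SE 0.27, adjusted p = 6.8e-10), each in 3 of 3 livers. UBASH3A (3.45), RGS1 (2.91) and the adhesion protein VCL (−5.11) were also among the 5 highest or 5 lowest. Without livers 1, 2 and 3 in turn, 400, 623 and 612 genes were higher, and 536 were lower without liver 1. Without the liver block the counts were 201 and 264, with sums thinned to equal UMIs 500 and 589, and with count splitting 660 and 578. DESeq2 gave 720 higher and each liver clustered on its own 657.

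Of 8 circulation genes, 8 were lower in CD56bright NK-like cells, also when adjusted over the list alone (median −3.22). CXCR1, a receptor of interleukin 8, had 2 UMIs against 196, a ratio of 420 (115 to 3496). Beside these genes, the 3 measured neutrophil markers, FCGR3B, CXCR2 and PROK2, had a median log2 fold change of −4.63 (−8.04 to −2.75), where FCGR3B is a near-identical copy of the CD16 gene FCGR3A. Of 11 cytotoxic genes 7 were lower and 1, FASLG, the death ligand (0.71), was higher, also when adjusted over the list alone (median −0.64). GZMA (−0.12) and KLRD1 (0.07) did not pass. Of 10 residency genes 5 were higher and 2 lower, or 6 and 2 when adjusted over the list alone (median 0.77). CXCR6 (4.66) and RGS1 were the largest, while ZNF683, the residency factor Hobit (−3.84), and RGS2 (−0.79) were lower and ITGA1 did not pass (−0.02). For these lists limma camera gave adjusted p = 7.5e-37 for circulation, 1.4e-06 for cytotoxic and 7.4e-06 for residency genes, and 2.0e-04, 0.0241 and 0.0452 with an estimated correlation. Here too the background lacked the variable genes used for clustering, so these values can be too small. GNLY, GZMB and S1PR5 of these lists were also among the leading genes of the CD16 NK-like cluster L8. The values thus describe a class that such genes lead and are no separate support for it. The residency list lost its call with list genes among the features, which left 2 genes (camera adjusted p = 0.0982). RGS2 lost its call under 5 alternatives by edgeR's quasi-likelihood test (adjusted p = 0.0503 to 0.358), with 0.308 without liver 1 and 0.112 without liver 2, and FASLG with no liver block (0.594).

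Of 12 cytokines and chemokines 6 were higher and 0 lower in CD56bright NK-like cells, or 7 and 0 when adjusted over the list alone (median 0.75), with the growth factor CSF2 (3.53) and LTA (1.78) the largest; IFNG (0.65) and TNF (0.03) did not pass. Of 11 transcription factors 6 were lower, among them BACH2 (−3.08) and TBX21, the factor T-bet of mature NK cells (−2.41), and 4 were higher, among them TOX2 and EOMES, T-bet's relative (1.49), also when adjusted over the list alone (median −0.88). Of 8 inhibitory receptors 3 were higher, with the ectonucleotidase ENTPD1 (4.10) and TIGIT (1.05) the largest, and 2 lower, HAVCR2 (−2.0) and KLRG1 (−1.36), also when adjusted over the list alone (median −0.76). Of 14 dissociation genes 9 were higher and 0 lower, also when adjusted over the list alone (median 0.42), led by FOS (2.42) and EGR1 (1.96). Limma camera gave adjusted p = 3.2e-06 for cytokines, 0.0080 for transcription factors, 0.506 for inhibitory receptors and 7.3e-09 for dissociation genes. With an estimated correlation the values were adjusted p = 0.0241, 0.149, 0.511 and 0.0381, so the call for transcription factors was lost, as it was in camera with no liver block (adjusted p = 0.495), with the stricter cell filter (0.0602) and with list genes among the features, which left 2 genes with a mean of 0.10 (0.55). In edgeR's quasi-likelihood test with no liver block, adjusted p was 0.199 for CSF2, 0.0752 for LTA, 0.390 for TBX21 and 0.367 for EGR1, and with each liver clustered on its own 0.0725 for CSF2. Beside these groups, 6 hepatocyte markers had a median log2 fold change of 1.76 (0.39 to 2.56), HBA1 and HBA2 a median of −4.74, 7 T cell markers a median of 0.10 (−2.98 to 2.59) and 4 cycling cell markers one of −1.48 (−5.18 to 0.79).

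**Figure D3:**
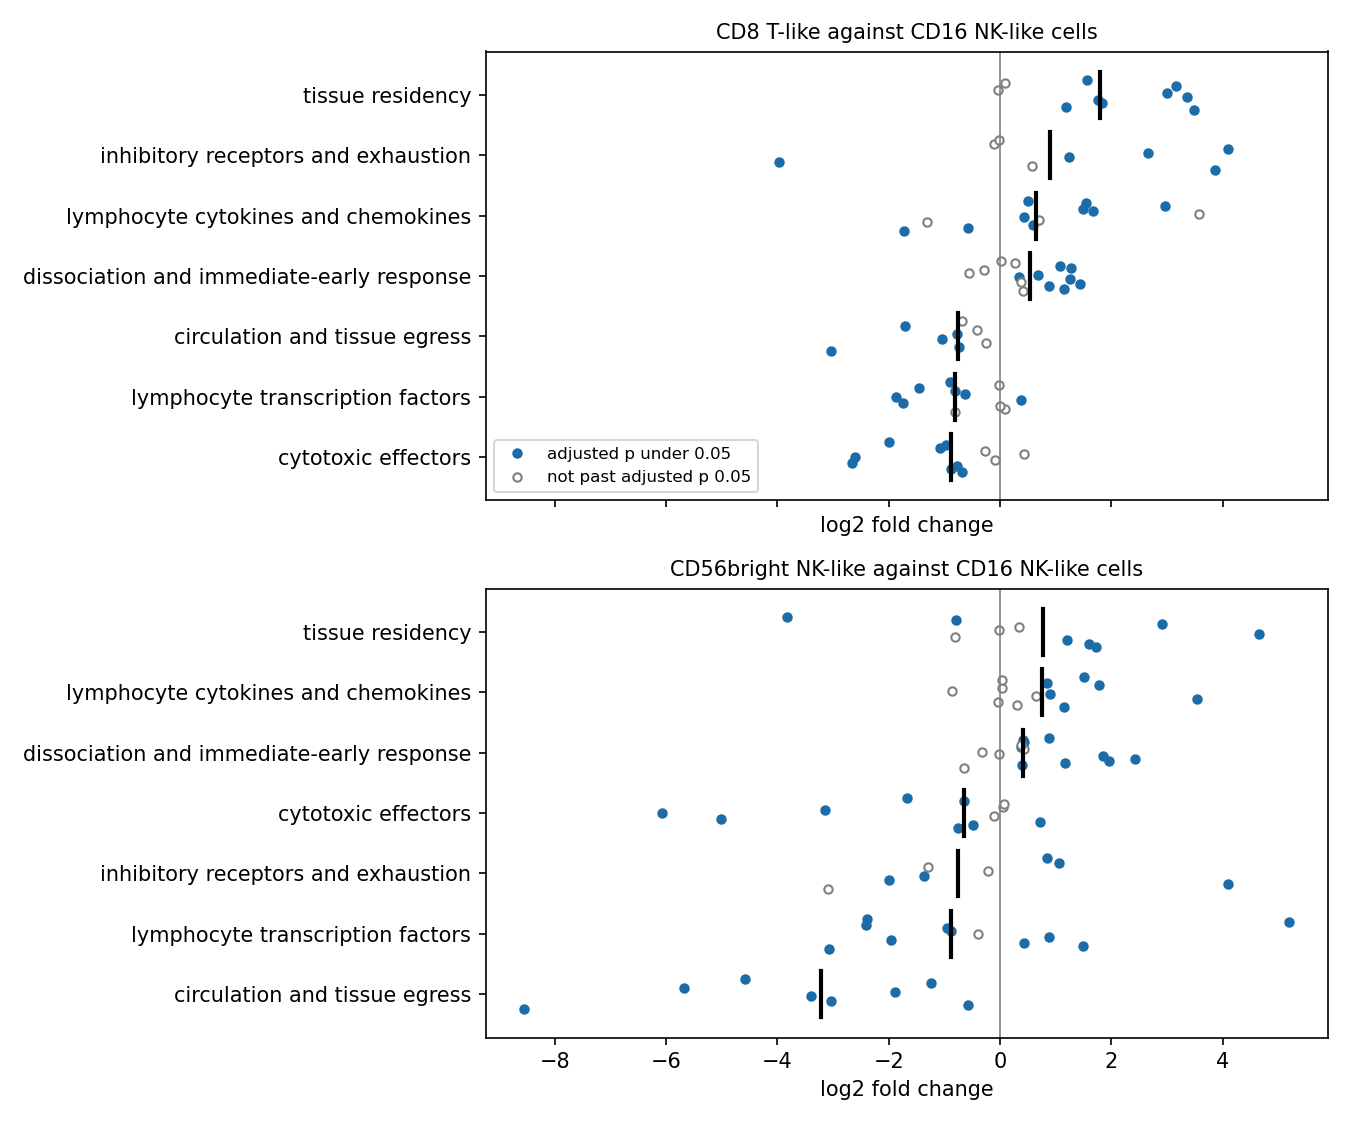
Log2 fold change (x axis) of each measured member of the fixed lists (y axis) for CD8 T-like and CD56bright NK-like cells, each against CD16 NK-like cells. Filled points had adjusted p under 0.05, open points did not, and black ticks mark list medians; for circulation genes these were −0.76 and −3.22.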

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

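In this part, the depth, dissociation and doublet score tests were fixed before their results were seen, and the tests by separate clustering, by shares of macrophages, by hepatocyte markers, by levels above all other clusters, by T and NK markers and by the lipid-associated list were chosen after the clusters had been seen. Cluster P3 and the 2 sets of cells named with it stand here because the comparisons did not use them.

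Cluster P3 held 125 phagocytes, 88, 1 and 36 in livers 1, 2 and 3, led by TREM2, CD9, FABP5, GPNMB and APOC1. Against the Kupffer-like cluster P5, 9 of 10 lipid-associated macrophage genes were higher and 0 lower, with a median log2 fold change of 6.09, or 5.51 with genes of 0 UMIs set at their bound, but the cluster was singled out by genes of this list, so the list cannot test whether a lipid-associated macrophage programme distinguishes P3, and that stays open. The dissociation list had a median of −0.10 against P5, under the limit set beforehand. Of its 14 genes 3 were higher, among them ATF3 (3.04), and 3 lower. Hepatocyte markers had a median of 0.20, far below the change of the lipid-associated list. Since the cluster was picked by genes of that list, the gap in size does not decide about free hepatocyte RNA. The median doublet score of 0.0924 lay above the 75th percentile of other phagocytes, 0.0882, as doublets would give. P3 was also deeper, with a median of 14318 UMIs against 9748. Cycling P13 (0.0984) and cDC2-like P16 (0.0889) lay above that percentile too, like the mixed clusters P7 (0.0986) and P9 (0.0914), so the score alone cannot decide. In P3, 8 of the 10 list genes lay above all 75 other cluster libraries, which excludes no doublets, since most of these genes led the cluster. Although some lymphocyte genes were higher than in P5, 12 T and NK markers stood at 0.903% (exact Poisson interval 0.661 to 1.20) of their level in lymphocyte clusters. This level was 22.2% to 28.99% in the mixed clusters P6, P7 and P9 and 0.197% in P5. The same markers had set which clusters were called mixed, so the contrast with P6, P7 and P9 was partly fixed in advance. The low level itself makes doublets with T or NK cells unlikely as the whole cause, and doublets of 2 phagocytes stay open.

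Kupffer-like cells were scarce in liver 2, where 3.44% (2.17 to 5.17) of phagocytes thinned to 2000 UMIs carried at least 3 of the 9 Kupffer markers, against 23.6% (21.8 to 25.6) and 9.07% (7.41 to 10.97) in livers 1 and 3, so lower depth is unlikely as the whole cause; 38, 122 and 48 cells were too shallow in livers 2, 1 and 3. Unthinned, the shares were 11.8%, 40.9% and 26.8%, at median depths of 7837, 11011 and 9670 UMIs, and cDC1-like cells, which should lack the markers, had 0 such cells after thinning, from a median of at least 15386 UMIs per liver. With the second level clustered per liver, liver 2 had 0 Kupffer-like cells. The first level and the scores behind names still used all livers, so whether joint clustering hid some cells stays open. After thinning, 22 phagocytes of liver 2 carried the markers, and 2 Kupffer-like cells did. These numbers were 467 and 287 in liver 1, and 96 and 38 in liver 3. An even loss would lower macrophages and monocytes alike. Monocyte-derived-like cells held 1.88% in liver 2, against 2.78% and 2.18% in livers 1 and 3, or up to 4.79% in liver 3 under alternatives. Non-classical monocyte-like cells held 1.63%, against 1.67% and 1.19%, while unnamed phagocytes were lower (0.189%, against 2.95% and 4.09%). Kupffer-like cells were 2.45% (0.673 to 6.16) of Kupffer-like plus monocyte-derived-like cells, against 54.9% and 23.1%. Relative to monocyte-derived-like cells, Kupffer-like cells were thus fewer in liver 2 than in livers 1 and 3. That share also differed between livers 1 and 3, so the share liver 2 would have had is unknown. An even loss therefore cannot be judged. A selective loss of Kupffer-like cells in digestion or sorting stays open, and no biological explanation was tested, since the design has 1 group.

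A set of 99 cells in liver 1 carried the leading genes of sinusoidal endothelium (CCL14, FCN3, CRHBP and CLEC4G), 1.02% (0.833 to 1.24) of its cells, although the sort was for CD45. Liver 2 had 0 of 8451 such non-immune cells, which allows a share of up to 0.0355% at a limit of 3 cells and 0.0436% by the exact 95% interval, and liver 3 had 2. Clusters P6, P7 and P9 held 331 cells with both phagocyte and T or NK genes, 202, 58 and 71 per liver, and were kept out of every comparison.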

How the results depend on the processing

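The alternatives here were chosen before the data were examined, except naming thresholds of 0.5 and 1 and the class without P12. Under the alternatives, 89 counts of genes stayed within 1.5 times the reported count and 27 did not. Lists kept direction and side of the threshold in 521 cases, lost the call in 15, 4 of them with list genes among the features, gained one in 25 and reversed in 4, and named genes kept them in 1739 cases, lost the call in 86 and reversed in 2. DESeq2 has no camera test, so lists were not run there; lists with no member left to test have no value with list genes among the features. Fry lost no call and gained 3, while camera with an estimated correlation lost 9. Since fry does not compare a list with other genes, its calls do not answer the question of camera. The 3 livers and the 50 Kupffer-like cells of liver 3 limit the depth of the first comparison.

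The pairing of classes within livers was used as a block. With no replicate block the monocyte-derived-like comparison gave 512 higher and 633 lower genes, the CD8 T-like comparison 284 and 245, and the CD56bright NK-like comparison 201 and 264. The call was lost for 26 named genes and for the transcription factors of CD56bright NK-like cells, and 2 lists gained one.

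With sums thinned to equal UMIs the counts were 449 and 459, 547 and 498, and 500 and 589 in the same order, with fewer UMIs and fewer genes tested. With only the 2 classes compared, 596 genes were higher in monocyte-derived-like cells. With count splitting, which leaves fewer UMIs to test, 652 genes were lower in CD8 T-like cells, and 660 were higher and 578 lower in CD56bright NK-like cells. For the latter, DESeq2 gave 720 higher genes and separate clustering 657; the cause was not tested. Leaving out each liver in turn gave 280 to 860 higher and 292 to 1045 lower genes for monocyte-derived-like cells, 431 to 763 and 445 to 730 for CD8 T-like cells, and 400 to 623 and 536 to 791 for CD56bright NK-like cells. Where liver 1 or 3 was left out, the lone Kupffer-like library was assumed to vary like the other classes.

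The mean share of CD8 T-like cells was 14.1% with no doublets removed, 18.7% with the automatic Scrublet threshold, 15.2% with each liver clustered on its own, 16.9% with list genes among the features and 6.20% at a naming threshold of 1. The share of CD56bright NK-like cells was 18.7% with the stricter cell filter. Monocyte-derived-like cells held 2.76% with no doublets removed, 3.40% with the automatic threshold, 3.52% with the stricter filter, 3.62% at resolution 0.5, 3.30% with list genes among the features, 3.61% with count splitting and 3.40% at a naming threshold of 0.5. The cDC2-like share was 2.19% with list genes among the features, the mature dendritic cell-like share 0.844% with no doublets removed and 0.780% with count splitting, and the non-classical monocyte-like share 1.88% with no doublets removed. Regulatory T-like cells held 0% with the stricter filter, at resolution 0.5, with separate clustering, with list genes among the features and with count splitting. The cause of these moves was not tested.

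With list genes among the features, which leaves few members to test, 3 lists reversed: the mean log2 fold change was −0.76 for inflammatory genes, 0.28 for MHC class II and 0.10 for transcription factors of CD56bright NK-like cells. CD9 was −0.61 at a naming threshold of 0.5, where cluster P11, in which CD9 was higher than in P5, joined the Kupffer-like class. Leaving out a liver gave −0.14 to 0.65 for the iron list and −3.15 to 2.90 for CXCL9, in both cases reversed without liver 1. The causes were not tested.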

Other observations

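These contrasts of clusters and the tests in them were chosen after the clusters had been seen, and the splits of libraries were planned.

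Between cluster P3 and the Kupffer-like cluster P5, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 786 genes higher and 669 lower of 8060. TREM2 had 1280 UMIs against 13 (log2 7.54, adjusted p = 8.3e-13), CD9 differed by 7.59, FABP5, a fatty acid carrier, by 4.63 and LGALS3 by 3.18. FABP4 had 2 UMIs in P5, a ratio of 2734 (756 to 22589), and SPP1 and LPL, the enzyme that frees fatty acids from lipoproteins, had 0 UMIs there and were at least 83.9-fold and 127-fold higher. CD63 did not pass (−0.40). Complement genes were lower in P3, 8 of 10 with 1 higher (median −2.34, limma camera adjusted p = 1.6e-11, or 0.00516 with an estimated correlation), C1QA by −2.26. Of 12 interferon response genes 10 were lower (median −1.64, limma camera adjusted p = 8.6e-10), a call lost with an estimated correlation (adjusted p = 0.0701). Some lymphocyte genes were higher in P3 by edgeR's quasi-likelihood test, at low levels: NKG7 had 45 UMIs against 18 (log2 2.21, adjusted p = 0.0279) and IL32 107 against 49 (1.88, adjusted p = 0.0134), CD69 and CRTAM differed by 2.25 and 2.67, and CTLA4 had 2 UMIs in P5, a ratio of 27.4 (6.94 to 237). Against the monocyte-derived-like cluster P0, P3 had 964 genes higher and 734 lower, and 10 of 10 lipid-associated macrophage genes were higher (median 5.86), a count that is no test, since genes of this list led the cluster. Of 10 MHC class II genes 10 were higher (median 2.56, camera adjusted p = 1.3e-21, or 0.00884 with an estimated correlation), and 11 of 17 lipid uptake, storage and efflux genes were higher with 1 lower (median 1.71, camera adjusted p = 1.2e-07, or 0.0160). Hepatocyte markers had a median of 1.89 in that contrast.

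Cluster P11, with 120, 0 and 94 cells in livers 1, 2 and 3, was led by SLC40A1, the iron exporter, and GPR34. Against P5, 438 genes were higher and 357 lower by edgeR's quasi-likelihood test. Complement genes were again lower, 6 of 10 with 0 higher (median −1.35, limma camera adjusted p = 1.1e-08, or 0.00560 with an estimated correlation), while C1QA did not pass (−0.83). TREM2 was higher by log2 5.24 and CD9 by 4.77. Of 10 lipid-associated macrophage genes 4 were higher and 1 lower, with a median of 0.83, or 0.37 with genes of 0 UMIs set at their bound. Limma camera gave adjusted p = 0.0230, a call lost with an estimated correlation at adjusted p = 0.263. Of 10 MHC class II genes 6 were higher (median 0.62, limma camera adjusted p = 2.3e-06, a call likewise lost at adjusted p = 0.109). Of 14 dissociation and immediate-early genes 6 were higher and 1 lower (median 0.57, limma camera adjusted p = 0.0014, or 0.109 with an estimated correlation), and hepatocyte markers had a median of 0.75.

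For each lymphocyte comparison the 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 1027 higher and 1005 lower genes for CD8 T-like cells against at most 1 and 0 in the other splits, and 1084 and 999 for CD56bright NK-like cells against at most 0 and 1. Only 1 split of each, the real one, gave as many genes. The classes were drawn by clustering the same cells, and every other split mixed both classes within its groups. The real split was thus bound to give the most genes, so the splits lend the calls no support.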
